A study of Drosophila melanogaster with 22 samples.

How the data were processed

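Messenger RNA was measured with 22 Affymetrix Drosophila expression arrays, each hybridised with biotin-labelled RNA made from 4 µg of total RNA, per the labels' protocols. The deposited table gave 1 intensity per probe set and array. The tool named in the submitters' processing notes was GCRMA, a method that corrects each probe's background from its base composition, normalizes the arrays to one another and summarises the probes of a set into a single value. The GCRMA version, its settings and the genome build behind the probe annotation were not given in the sources used here. The deposited intensity values lay on a linear scale, from 2.02 to 70939, and no 2 arrays held the same set of values, so the log2 of each value was taken before any step below. GCRMA pulls the weakest probes towards a common low value, which shrinks fold changes of weakly expressed transcripts. Normalization between arrays also fixes the overall level, so a uniform change of all transcripts could not be seen here.

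The table held 18952 probe sets, of which 183 were hybridisation controls and were left out. In the platform annotation used here 13647 of the others had a single gene symbol, 402 had several and 4720 were unnamed. Of those with a single symbol, 13544 were found by gene identifier in a table of current gene names, which changed no symbol, and 103 kept the name of the annotation. That table was used only for names and for which genes lie next to each other, and no coordinate is given, since the build of the array annotation was not known. A probe set was kept if its log2 value was 4 or more (an intensity of 16 or more) on at least 2 arrays, which left 7289, of which 6403 had a single symbol. For genes with several such probe sets, which were 329, the set with the highest mean over the 22 arrays represented the gene. In all 5961 genes were tested. Several genes of the lists below were unnamed or under this floor and were not analysed here. The arrays carried no detection calls in the values used here, so a level below 16 is described as below the floor and a fold change against it depends on the background correction. The number of arrays limits the precision. The SD within groups, moderated across genes by eBayes in the fit described below, was 0.0793 on the log2 scale for the median gene.

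Groups were taken from the sample titles, which name the dsRNA and a replicate number. A linear model with 1 mean per group was fitted to all 22 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with 16 residual degrees of freedom), so that the Cdk8 group with its 2 arrays shared the estimate of spread with the other groups. Each knockdown was compared with the mean of the GFP and Luc group means (8 arrays). The controls were compared with each other, Med12 with Med13, Cdk8 with CycC, and the mean of Med12 and Med13 with the mean of Cdk8 and CycC, a contrast in which the controls drop out. Tests were two-sided, and p-values were adjusted over the 5961 genes by the Benjamini-Hochberg method with a threshold of 0.05. A gene is said to have risen, fallen or changed only if it passed that threshold.

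The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The text names the 8 largest rises and 8 largest falls in each knockdown and in the contrast of the pairs, among genes past the threshold for which every array of the group lay beyond every array it was compared with. It names the 3 largest each way in the smaller contrasts, the 4 module genes, and for each list the 4 measured members with the smallest p in the F-test over the 4 knockdowns. Lists of genes covered Mediator, immunity, blood cell types, signalling, metabolism, the cell cycle, protein synthesis and folding, RNA interference and markers of other tissues. Lists with at least 5 measured genes were tested with camera, which asks whether the genes of a list shift relative to all other genes, with a preset correlation of 0.01 between genes and adjustment over the lists of a contrast. Camera with a correlation estimated from the data and fry were alternatives. Fry's directional p asks whether the genes of a list move on balance one way, its mixed p whether they change in either direction, and neither compares a list with other genes.

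The 4 knockdowns share their controls, so fold changes of unrelated groups would still correlate. The size of this effect was obtained from 50 simulations of unchanged groups set against the same controls, and every correlation and overlap was also computed with one knockdown set against GFP and the other against Luc. The fit was tested on simulated data of 5961 genes, in which 67 were changed by a log2 value of 0.25, 67 by 0.5 and 66 by 1. At 0.25, the share recovered was 52.2% in the Cdk8 comparison, 77.6% for CycC, 79.1% for Med12 and 83.6% for Med13. At 0.5 it was 98.5%, 97.0%, 98.5% and 100% in the same order. At 1 all were recovered in these 4 comparisons, and the share of false calls in them lay between 3.68% for CycC and 5.65% for Cdk8. The simulated noise was independent between arrays and followed the fitted model, so a false share near the threshold was built in. Fewer genes were changed than were called in the data. The simulation therefore cannot show the effect of deviations shared between arrays. Alternatives covered the scaling between arrays, the floor, the choice of probe set, the controls, the arrays in the fit, array weights, the prior, the replicate number as a block and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.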

Results

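The study measured messenger RNA in S2 cells, a cultured line from Drosophila melanogaster embryos that resembles blood cells (haemocytes), after depletion of each subunit of the Cdk8 module of Mediator. Mediator is the coactivator complex that connects transcription factors with RNA polymerase, and the module consists of the kinase Cdk8, its partner Cyclin C (CycC), Med12 and Med13, of which the last pair is encoded in flies by kto and skd. The question was what the loss of each subunit does to gene expression. Depletion was by double-stranded RNA (dsRNA), which S2 cells take up and cut into short RNAs that direct the destruction of matching transcripts. Cells received 20 µg of dsRNA and were collected after 72 h. There were 2 arrays for Cdk8 dsRNA and 4 each for CycC, Med12 and Med13 dsRNA. The 8 controls were 4 arrays with dsRNA against GFP and 4 with dsRNA against luciferase (Luc), reporter genes that fly cells lack. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Between 7175 and 7214 probe sets per array lay at or over the floor, and the lowest correlation between 2 arrays of a group was 0.996.

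The targeted transcripts came first. Cdk8 mRNA fell to 14.4% of the control level under Cdk8 dsRNA (log2 mean 4.72 ± 0.12 SD, n = 2, against 7.52 ± 0.03, n = 8; adjusted p = 1.02e-18). CycC mRNA fell to 3.56% under CycC dsRNA (4.39 ± 0.29, n = 4, against 9.20 ± 0.05; adjusted p = 1.72e-20). The transcript for Med12, kto, fell to 9.98% under Med12 dsRNA (5.34 ± 0.09, n = 4, against 8.67 ± 0.08; adjusted p = 2.16e-19). The transcript for Med13, skd, fell to 80.6% under Med13 dsRNA (8.68 ± 0.12, n = 4, against 8.99 ± 0.08; adjusted p = 7.76e-05), although each of these arrays lay below all 8 controls. The second skd probe set stood at 88.1% of controls (7.55 ± 0.32, n = 4, against 7.73 ± 0.10, n = 8). The labels do not place the dsRNA on the transcript, so neither probe set can be set against the targeted part. Depletion of a subunit left the other module transcripts between 92.5% and 121% of controls, and the call among these was skd, which rose to 121% under Med12 dsRNA (adjusted p = 0.000228).

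**Figure D1:**
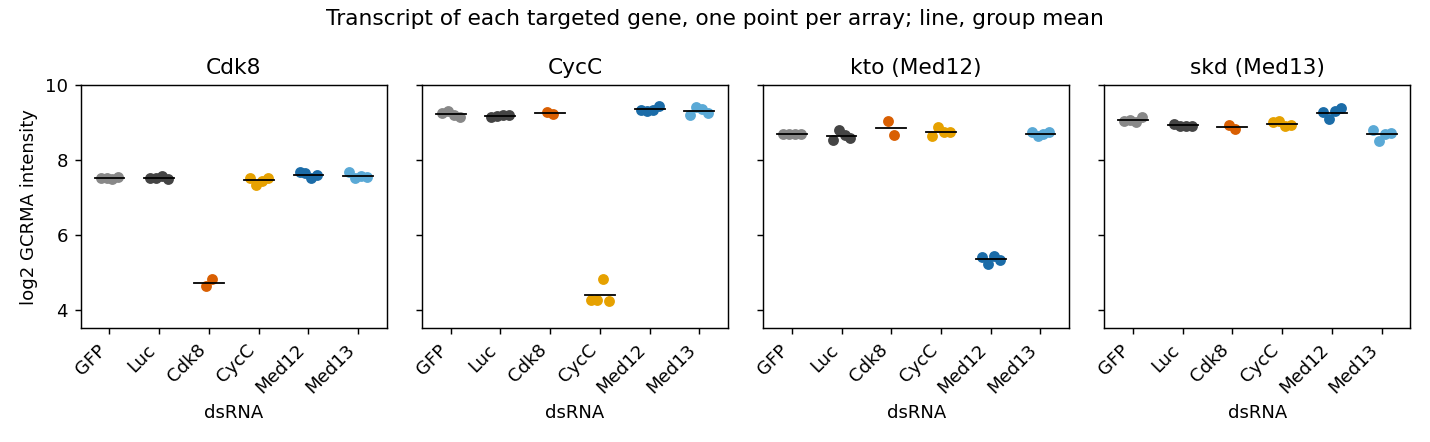
Log2 GCRMA intensity (vertical axis) of the 4 module transcripts on each of the 22 arrays, grouped by dsRNA (horizontal axis); points are arrays and lines are group means. Cdk8, CycC and kto drop to means of 4.72, 4.39 and 5.34 under their own dsRNA, while skd under Med13 dsRNA has a mean of 8.68 against 8.99 in the controls.

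The arrays fell into 3 sets along their main axes of variation. The first principal component of the tested genes held 51.0% of the variance and set the 8 Med12 and Med13 arrays apart from all others. The second held 18.4% and set the 6 Cdk8 and CycC arrays apart from the 8 controls. The GFP and Luc controls differed in 2 genes of 5961. ATPsyndelta, a subunit of mitochondrial ATP synthase, was higher with GFP dsRNA by 0.44 ± 0.04 on the log2 scale (SE, n = 4 each), and mRpS25, a mitochondrial ribosomal protein gene, was lower by a log2 difference of -0.47 ± 0.05. At an unadjusted p of 0.05, 331 genes passed against 298 by chance alone. The count of 2 became 10 without the Luc 4 array and 4 without either Cdk8 array.

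**Figure D2:**
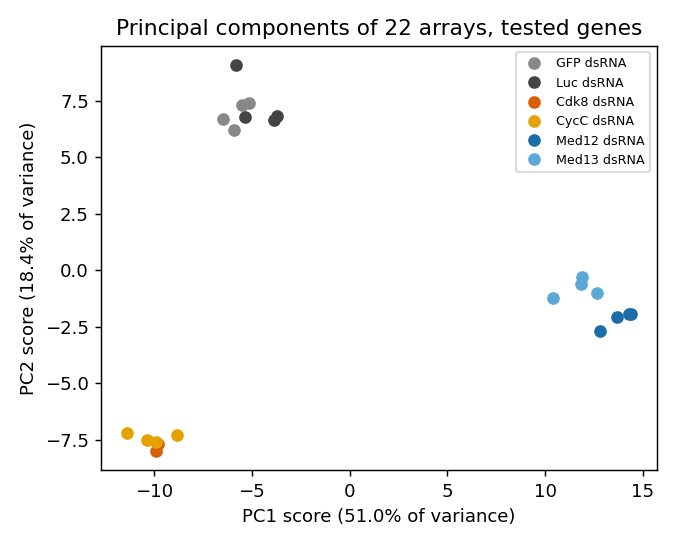
Scores of the 22 arrays on the first (horizontal axis, 51.0% of variance) and second (vertical axis, 18.4%) principal components of the tested genes, coloured by dsRNA. The Med12 and Med13 arrays lie on one side of the first axis, and the Cdk8 and CycC arrays are separated from the GFP and Luc arrays along the second.

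Depletion of Cdk8 raised genes of DNA replication and lowered genes of antimicrobial peptides. The largest rises were in Argk1, which encodes an arginine kinase (8.34-fold, log2 3.06 ± 0.21 SE), and bam, a differentiation factor of the germline (5.67-fold, 2.50 ± 0.15), whose 8 control arrays all lay below the floor. The cytochrome P450 gene Cyp4ac1 (3.01-fold), the adhesion gene Fas1 (2.77-fold) and trol, which encodes the matrix proteoglycan perlecan (2.61-fold) followed, with the uncharacterised genes CG12493 (3.15-fold), CG10939 (2.72-fold) and CG15482 (2.49-fold). Of 3 other trol probe sets over the floor, 2 shared its direction. The largest falls were in CG33462 (8.47-fold lower, log2 -3.08 ± 0.14), Cdk8 itself, the antifungal peptide gene Mtk (5.13-fold lower, -2.36 ± 0.24) and CG10359 (3.06-fold lower). Next came GrlHz (2.90-fold lower, with both Cdk8 arrays below the floor), the antibacterial peptide gene DptB (2.75-fold lower, -1.46 ± 0.11), gas (2.63-fold lower) and CG44014 (2.62-fold lower). In all 632 genes rose and 481 fell, with a median size of 0.26 on the log2 scale, and 35 of them changed 2-fold or more. The count of 1113 was 538 without the Cdk8 1 array and 623 without the Cdk8 2 array, where the lone array left is assumed to vary like those of the other groups.

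The antimicrobial peptide genes fell together after Cdk8 depletion. All 6 measured members fell, and all 6 also when adjusted over the list alone, with edin, a gene induced by infection, at -1.15 ± 0.08 and AttD at -1.01 ± 0.13 beside Mtk and DptB. For this list camera gave adjusted p = 1.27e-11, and adjusted p = 0.00413 with an estimated correlation. Of 13 measured plasmatocyte receptor and phagocytosis genes 7 fell and none rose, 7 down and 1 up when adjusted over the list alone, among them the phagocytic receptor eater (-0.51 ± 0.06). The camera test of these genes gave adjusted p = 9.37e-05, and adjusted p = 0.0410 with an estimated correlation. Of the 30 measured cell cycle and DNA replication genes 21 rose and none fell (23 up and 1 down adjusted over the list alone), including the replication licensing factor dup (0.48 ± 0.05), the helicase subunits Mcm6 (0.45 ± 0.04) and Mcm2 (0.42 ± 0.05) and the ribonucleotide reductase gene RnrL (0.43 ± 0.04). For that list camera gave an adjusted p = 6.80e-13, and adjusted p = 0.0253 with an estimated correlation. In the glutathione and xenobiotic list 9 of 25 fell and 1 rose, 11 and 1 adjusted over the list alone, with Cyp4e2 at -0.68 ± 0.09 and GstO3 at -0.58 ± 0.06 but GstD5 at 0.32 ± 0.09. Its camera adjusted p = 2.79e-05 was lost with the other test, adjusted p = 0.119 with an estimated correlation. Of 7 crystal cell and melanisation genes 3 fell, and 4 adjusted over the list alone, among them the clotting and melanisation protease gene Sp7 (-0.49 ± 0.06), the serpin gene Spn77Ba (-0.42 ± 0.09) and the prophenoloxidase gene PPO3 (-0.48 ± 0.07). As a list they had camera adjusted p = 0.0168, but adjusted p = 0.179 with an estimated correlation. Of 9 blood transcription factor and PDGF/VEGF pathway genes 3 rose, 4 adjusted over the list alone, namely the ligand gene Pvf1 (0.61 ± 0.05), its receptor gene Pvr (0.15 ± 0.04) and the GATA cofactor gene ush (0.28 ± 0.07). In the camera test this list had adjusted p = 0.00789, but adjusted p = 0.179 with an estimated correlation. Of 11 homeotic and Polycomb genes 5 rose, 7 adjusted over the list alone, with Psc at 0.43 ± 0.09 and Sfmbt at 0.32 ± 0.06. Tested with camera they had adjusted p = 0.00957, but adjusted p = 0.335 with an estimated correlation.

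Depletion of Cyclin C also raised Argk1, bam and trol and lowered Mtk and DptB. Argk1 rose 6.24-fold (log2 2.64 ± 0.16 SE, n = 4 against 8), bam 4.29-fold, CG12493 3.15-fold and Fas1 2.82-fold. There were also rises in Cyp4ac1 (2.76-fold), trol (2.60-fold), CG15482 (2.52-fold) and Pxn, which encodes the matrix enzyme peroxidasin (2.41-fold). After CycC itself the largest falls were in CG33462 (7.59-fold lower, log2 -2.92 ± 0.11), Mtk (5.36-fold lower, -2.42 ± 0.19) and GrlHz (3.09-fold lower, with all 4 CycC arrays below the floor). Then followed DptB (2.80-fold lower), CG31445 (2.38-fold lower), gas and CG4793 (each 2.24-fold lower). In all 797 genes rose and 648 fell (1445, of which 29 by 2-fold or more), with a median size of 0.21 on the log2 scale.

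All 6 antimicrobial peptide genes fell under CycC dsRNA too, and all 6 when adjusted over the list alone (edin -0.96 ± 0.06, AttD -1.01 ± 0.10). For this list camera gave adjusted p = 8.29e-11, and adjusted p = 0.00597 with an estimated correlation. Of the 30 cell cycle and DNA replication genes 23 rose and none fell (24 up and 1 down adjusted over the list alone; dup 0.49 ± 0.04, RnrL 0.45 ± 0.03). The camera test of these genes gave adjusted p = 9.58e-15, and adjusted p = 0.0146 with an estimated correlation. Of the 13 plasmatocyte genes 8 fell, 9 adjusted over the list alone (eater -0.59 ± 0.05). As a list they had camera adjusted p = 4.50e-05, and adjusted p = 0.0289 with an estimated correlation. Of 15 Imd pathway and peptidoglycan recognition genes 6 fell, and 6 fell and 1 rose adjusted over the list alone. They included PGRP-LF (-0.55 ± 0.04), a receptor that restrains the pathway, PGRP-LA (-0.36 ± 0.06) and the NF-κB factor gene Rel (-0.09 ± 0.03). In the camera test this list had adjusted p = 0.0368, lost after quantile normalization, and adjusted p = 0.321 with an estimated correlation. In the glutathione and xenobiotic list 9 of 25 fell and 2 rose (10 and 2 adjusted over the list alone). Tested with camera they had adjusted p = 0.00438, but adjusted p = 0.345 with an estimated correlation. Of 11 homeotic and Polycomb genes 6 rose (7 up and 1 down adjusted over the list alone; Psc 0.39 ± 0.07). For this list camera gave adjusted p = 0.0284, but adjusted p = 0.349 with an estimated correlation.

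Tested directly against each other, Cdk8 and CycC depletion differed in 6 genes of 5961. Besides both targets these were CG9164 (log2 0.85 ± 0.16 higher with Cdk8 dsRNA, with all 4 CycC arrays below the floor), the cAMP phosphodiesterase gene dnc (0.65 ± 0.13 higher), the translation elongation factor gene eEF1gamma (0.47 ± 0.03 higher) and CG10359 (-0.55 ± 0.09). Of these eEF1gamma lay outside the rule for named genes and was chosen after its value was seen. At an unadjusted p of 0.05, 290 genes passed against 298 by chance. The count was 3 without the CycC 1 array and 3 without the CycC 2 array.

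Med12 dsRNA gave the largest count of changed genes and lowered haemocyte surface receptors. The counts do not rank the subunits, since kto fell to 9.98% of controls and skd to 80.6%, and the Cdk8 group had 2 arrays. Tested directly, Med12 and Med13 dsRNA differed in 52 genes. TwdlE, a gene of the Tweedle family of cuticle proteins, fell 12.2-fold (log2 -3.61 ± 0.13 SE, n = 4 against 8), with every Med12 array below the floor. After kto itself the next falls were in sn, which encodes the actin-bundling protein fascin (7.42-fold lower, -2.89 ± 0.15), the haemocyte surface gene He (7.40-fold lower, to below the floor on every Med12 array), the phagocytic receptor gene NimC4 (6.83-fold lower, -2.77 ± 0.11) and Mtk (6.13-fold lower, -2.62 ± 0.19). Those in CG31445 (5.64-fold lower) and CG4250 (5.30-fold lower, to below the floor on every Med12 array) came after them. The Med12 mean of NimC4, log2 3.90, also lay below the floor. The largest rises were in CG30148 (4.53-fold, log2 2.18 ± 0.09), CG9098 (4.14-fold, with all 8 controls below the floor), the gap junction gene ogre (4.00-fold, 2.00 ± 0.12) and Epac, a cAMP-regulated exchange factor (3.85-fold). After them came Fie (3.61-fold), CG11686 (3.32-fold), CG7702 (3.29-fold) and the odorant-binding protein gene Obp56h (3.10-fold). In all 1577 genes rose and 922 fell (2499), with a median size of 0.22 on the log2 scale, and 72 changed 2-fold or more. This balance depended on the scaling of the arrays, with 1331 higher and 1130 lower after centring each array on its median and 1297 higher and 1110 lower after quantile normalization.

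Of the 13 plasmatocyte genes 8 fell under Med12 dsRNA and none rose (the same adjusted over the list alone). Besides NimC4 and He they included the scavenger receptor gene Sr-CI (-2.32 ± 0.09) and eater (-1.07 ± 0.05). The camera test of these genes gave adjusted p = 6.94e-08, and adjusted p = 0.00950 with an estimated correlation. Of the 6 antimicrobial peptide genes 5 fell and 1 rose, also adjusted over the list alone. AttD (-0.82 ± 0.10), edin (-0.22 ± 0.06) and Mtk fell and DptB rose (0.29 ± 0.08). As a list they had camera adjusted p = 0.00248, but adjusted p = 0.228 with an estimated correlation. Of 15 Imd pathway and peptidoglycan recognition genes 8 rose and 1 fell, also adjusted over the list alone, among them the amidase gene PGRP-LB (0.76 ± 0.05), PGRP-LF (0.38 ± 0.04), PGRP-LA (0.36 ± 0.06) and Rel (0.32 ± 0.03). In the camera test this list had adjusted p = 0.0177, but adjusted p = 0.228 with an estimated correlation. Of 15 basement membrane and matrix genes 7 fell, and 9 fell and 1 rose adjusted over the list alone, with Pxn at -0.92 ± 0.07, Glt at -0.63 ± 0.04 and Tig at -0.38 ± 0.05. Tested with camera they had adjusted p = 0.00145, but adjusted p = 0.228 with an estimated correlation. Of 17 genes of the unfolded protein response and endoplasmic reticulum 9 fell and 2 rose, also adjusted over the list alone, including the neurotrophic factor gene Manf (-0.27 ± 0.03), the chaperone gene Gp93 (-0.32 ± 0.04) and the translocon gene Sec61beta (-0.20 ± 0.03). For this list camera gave adjusted p = 0.00955, but adjusted p = 0.233 with an estimated correlation. In the blood transcription factor list 6 of 9 fell and 2 rose, 7 and 2 adjusted over the list alone, with Pvf2 at -0.35 ± 0.06 and ush at -0.30 ± 0.05. The camera test of these genes gave adjusted p = 0.0205, but adjusted p = 0.233 with an estimated correlation. The calls for these last 2 lists were also lost after quantile normalization. In the glutathione and xenobiotic list 10 of 25 fell and 2 rose, also adjusted over the list alone, with Cyp6a8 at -1.51 ± 0.15 and GstD5 at -1.06 ± 0.07. As a list they had camera adjusted p = 0.00262, but adjusted p = 0.233 with an estimated correlation.

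Depletion of Med13 also lowered TwdlE, Mtk, He, NimC4 and sn, although skd stayed at 80.6% of controls. TwdlE fell 15.2-fold (log2 -3.93 ± 0.13 SE, n = 4 against 8; every Med13 array below the floor), Mtk 9.54-fold (-3.25 ± 0.19), He 6.14-fold and NimC4 6.04-fold. Further falls were in Sr-CI (5.94-fold, -2.57 ± 0.09), CG31445 (5.83-fold), CG5397 (4.89-fold) and sn (4.63-fold, -2.21 ± 0.15). The Med13 mean of He, log2 3.67, also lay below the floor. The largest rises were in CG30148 (6.17-fold, log2 2.62 ± 0.09), Obp56h (5.92-fold, 2.57 ± 0.16), ogre (3.62-fold), Fie (3.48-fold), CG9098 (3.00-fold, with all 8 controls below the floor), CG5001 (2.92-fold), CG7702 (2.87-fold) and CG11686 (2.78-fold). In all 1249 genes rose and 669 fell (1918, of which 55 by 2-fold or more). The balance between rises and falls again depended on the scaling, with 943 higher and 911 lower after centring each array on its median and 1030 higher and 842 lower after quantile normalization.

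Of the 13 plasmatocyte genes 8 fell under Med13 dsRNA, also adjusted over the list alone (eater -0.87 ± 0.05). In the camera test this list had adjusted p = 4.77e-08, and adjusted p = 0.00863 with an estimated correlation. Of 6 antimicrobial peptide genes 4 fell and DptB rose (0.25 ± 0.08), with the same numbers adjusted over the list alone (AttD -1.12 ± 0.10). Tested with camera they had adjusted p = 0.00112, but adjusted p = 0.166 with an estimated correlation. Of 15 Imd pathway genes 8 rose and 1 fell, also adjusted over the list alone (PGRP-LB 0.51 ± 0.05). For this list camera gave adjusted p = 0.0201, but adjusted p = 0.218 with an estimated correlation. Of 15 basement membrane and matrix genes 7 fell, also adjusted over the list alone (Pxn -1.25 ± 0.07, Glt -0.66 ± 0.04). The camera test of these genes gave adjusted p = 0.000158, but adjusted p = 0.166 with an estimated correlation. Of the 30 cell cycle genes 15 rose and none fell, 16 adjusted over the list alone, by small amounts such as 0.15 ± 0.03 for Mcm6 and 0.18 ± 0.03 for RnrL. As a list they had camera adjusted p = 0.0201, but adjusted p = 0.535 with an estimated correlation. Under Med12 dsRNA 11 of these genes rose, also adjusted over the list alone. In the camera test this list had adjusted p = 0.113. The other 4 lists past the threshold were led by the unfolded protein response and endoplasmic reticulum (6 of 17 fell and 1 rose, 9 and 3 adjusted over the list alone) and the blood transcription factors (5 of 9 fell and 2 rose, 6 and 2 adjusted over the list alone). They also held the glutathione and xenobiotic list (8 of 25 fell and 4 rose, 9 and 4 adjusted over the list alone) and lipid synthesis (6 of 20 fell and 4 rose, 7 and 4 adjusted over the list alone; the ethanolamine kinase gene eas -0.34 ± 0.05). Their camera adjusted p were 0.0199, 0.0237, 0.0237 and 0.0353, all lost after quantile normalization and at adjusted p = 0.303, adjusted p = 0.303, adjusted p = 0.468 and adjusted p = 0.465 with an estimated correlation.

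Set against each other, Med12 and Med13 depletion differed in 52 genes, 13 higher and 39 lower with Med12 dsRNA. Besides kto (log2 -3.36 ± 0.07) and skd (0.58 ± 0.06), the glycogenin gene Gyg (0.79 ± 0.15) and Ypel (0.68 ± 0.11) were higher with Med12 dsRNA, and Obp56h (-0.93 ± 0.18) and the gluconeogenic enzyme gene fbp (-0.67 ± 0.12) were lower. The count was 25 without the Med12 3 array and 34 without the Med13 4 array, and 33 with only these 8 arrays in the fit.

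**Figure D3:**
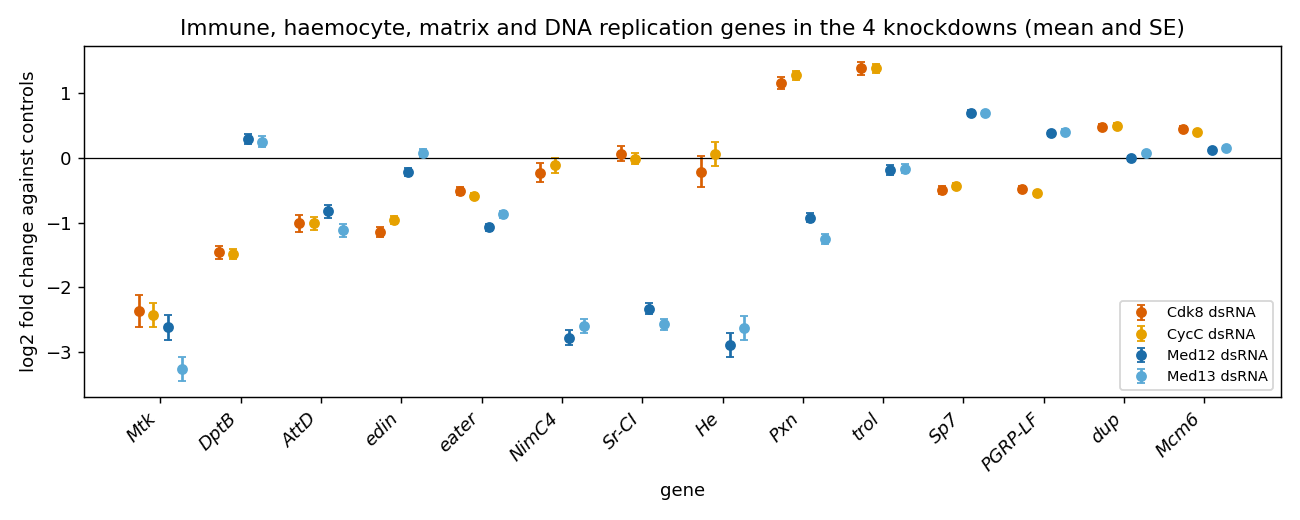
Log2 fold change against the controls (vertical axis; points are estimates, bars are SE) of 14 named genes (horizontal axis) in each of the 4 knockdowns. Mtk and AttD are lower in all 4, NimC4, Sr-CI and He fall with Med12 and Med13 dsRNA, and DptB, Pxn, Sp7 and PGRP-LF go opposite ways in the pairs.

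The responses formed 2 pairs. Across genes, which are not independent replicates, the fold changes for Cdk8 and CycC had a Pearson r of 0.856 and a Spearman rho of 0.818, and those for Med12 and Med13 an r of 0.923 and a rho of 0.880. The 4 correlations across the pairs lay between r = 0.112 (CycC with Med13, rho 0.116) and r = 0.134 (Cdk8 with Med12, rho 0.116). Without the 4 module genes r was 0.913 for Cdk8 with CycC, 0.935 for Med12 with Med13 and 0.119 to 0.139 across the pairs. Unchanged groups simulated against the same controls gave a mean r of 0.260 for Cdk8 with CycC, 0.330 for Med12 with Med13 and 0.258 to 0.333 across the pairs. The covariances, to which shared controls add a fixed amount, were 0.0374 for Cdk8 with CycC against 0.00122 simulated and 0.0631 for Med12 with Med13 against 0.00119 simulated. Across the pairs they were 0.00560 to 0.00795 against 0.00120 to 0.00121 simulated. With the controls split between the 2 knockdowns, r was 0.793 or 0.800 for Cdk8 with CycC and 0.881 or 0.887 for Med12 with Med13. Across the pairs it was 0.126 to 0.150 with Cdk8 or CycC set against GFP and 0.0380 to 0.0662 with them set against Luc.

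Of the genes that changed, 898 moved the same way under Cdk8 and CycC dsRNA and 0 moved in opposite ways, where independent lists would share 137 and 133. Under Med12 and Med13 dsRNA 1640 moved the same way and 1 the opposite way, against 434 and 370 for independent lists. The simulations of unchanged groups gave means of 0 in either class, but they held no changed genes. They therefore cannot show how far shared controls raise the overlap of genes that did change. With split controls 629 and 662 genes were shared by the first pair and 1178 and 1231 by the second. Across the pairs 352 to 441 genes moved the same way, where independent lists would share 186 to 311, and 210 to 330 moved in opposite ways, where 172 to 295 would. The figures for independent lists take no account of the shared controls. Genes called the same way in all 4 knockdowns numbered 270 (143 higher and 127 lower), among them Mtk, AttD and eater, which fell, and Fas1, Cyp4ac1 and MED1, which rose. MED1, a core Mediator subunit gene, rose by log2 0.34 ± 0.07, 0.35 ± 0.05, 0.19 ± 0.05 and 0.29 ± 0.05 in the order Cdk8, CycC, Med12 and Med13.

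The direct contrast of the mean of Med12 and Med13 with the mean of Cdk8 and CycC, which uses no controls, called 2928 genes, 1602 higher and 1326 lower with Med12 and Med13 dsRNA, of which 101 by 2-fold or more. More were lower than higher under other scalings, 1574 against 1451 after median centring and 1529 against 1478 after quantile normalization. TwdlE was 23.1-fold lower with Med12 and Med13 dsRNA (log2 -4.53 ± 0.12 SE, n = 8 against 6), Argk1 12.4-fold, sn 10.2-fold and He 6.39-fold lower. NimC4 was 5.71-fold, bam 5.65-fold, Sr-CI 5.56-fold and Pxn 4.92-fold lower. All 8 Med12 and Med13 arrays lay below the floor for TwdlE, Argk1 and bam. For He and NimC4 the means of these arrays, log2 3.53 and 3.98, also lay below it. The genes higher by the most were CG33462 (9.88-fold, log2 3.31 ± 0.10), CG30148 (5.46-fold), CG5001 (4.92-fold), ogre (4.64-fold), CG13252 (4.08-fold), Obp56h (3.80-fold), Fie (3.71-fold) and CG7702 (3.66-fold). For CG5001 the mean of the Cdk8 and CycC arrays, log2 3.96, lay below the floor. By list, 9 of 15 Imd pathway genes were higher with Med12 and Med13 dsRNA and none lower (camera adjusted p = 0.00219), and 10 of 15 matrix genes were lower and 1 higher (0.000110). There were also 6 of 9 blood transcription factor genes lower and 2 higher (0.00466), 21 of 30 cell cycle genes lower and 3 higher (4.53e-06) and 12 of 17 endoplasmic reticulum genes lower and 3 higher (0.00913). In the same order the counts adjusted over the list alone were 9 and 0, 12 and 1, 7 and 2, 22 and 3, and 13 and 3. The first 4 of these lists had adjusted p = 0.171 and the last adjusted p = 0.254 with an estimated correlation.

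Some genes moved in opposite directions in the pairs. With calls in all 4 knockdowns, 54 genes rose under Cdk8 and CycC dsRNA and fell under Med12 and Med13 dsRNA, and 115 did the reverse. These 169 compare with 121 for independent calls in the pairs, and the 270 genes that moved the same way in all 4 compare with 126. Independent calls take no account of the shared controls, and an error in these would move all 4 knockdowns the same way. The 126 may therefore be too low, and the 270 were not counted again with split controls. They include mRpS25, which differed between GFP and Luc. Argk1, Pxn, TwdlE, sn, Pvf1 and GstD5 were in the first class, with Pxn at 1.15 ± 0.09 and 1.27 ± 0.07 under Cdk8 and CycC dsRNA and at -0.92 ± 0.07 and -1.25 ± 0.07 under Med12 and Med13 dsRNA. The control mean of Argk1 was log2 4.12 ± 0.35 SD, near the floor, and its Med12 and Med13 arrays lay below the floor. Its fall therefore depends on the background correction. In the second class were DptB, PGRP-LF, the protease gene Sp7 (-0.49 ± 0.06, -0.44 ± 0.05, 0.69 ± 0.05 and 0.68 ± 0.05 in the order Cdk8, CycC, Med12 and Med13) and the fungal recognition gene GNBP3 (-0.52 ± 0.08, -0.58 ± 0.06, 0.58 ± 0.06 and 0.51 ± 0.06). With the pairs set against different controls, 106 or 152 genes were opposite, the former with Cdk8 and CycC against GFP.

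**Figure D4:**
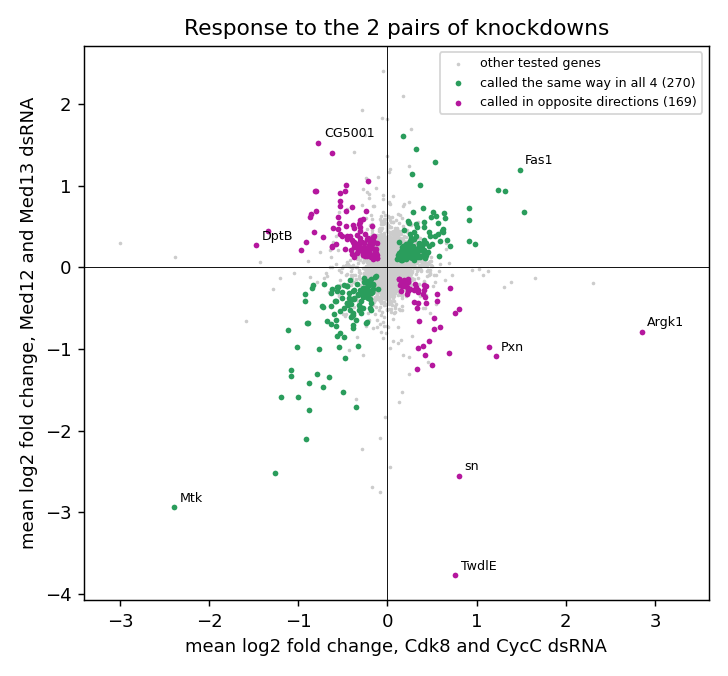
Mean log2 fold change under Cdk8 and CycC dsRNA (horizontal axis) against that under Med12 and Med13 dsRNA (vertical axis), 1 point per tested gene. The 270 genes called the same way in all 4 knockdowns are green and the 169 called in opposite directions by the pairs are magenta. TwdlE, Argk1 and sn lie far out at the lower right, and the control mean of Argk1 is near the floor.

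The lists that follow did not pass the camera test in any of these 5 contrasts, though some held genes that changed. Of 26 cytosolic ribosomal protein genes, such as RpL17 and RpS12, 0 passed the limma test in any knockdown, also adjusted over the list alone, and 0, 1, 1 and 0 had an unadjusted p under 0.05 in the order Cdk8, CycC, Med12 and Med13. Of 23 mitochondrial respiration genes 0 passed the limma test under Cdk8 or CycC dsRNA (2 and 3 at an unadjusted p under 0.05), 3 rose under Med12 dsRNA, such as ND-20 (0.11 ± 0.04), and 1 under Med13 dsRNA, and adjusted over the list alone none did. In the RNA interference list the Piwi-family gene aub rose by 1.20 ± 0.10 and 1.05 ± 0.08 under Cdk8 and CycC dsRNA, and 4 of 14 genes rose and 0 fell by the limma test, then 5 rose and 1 fell (6 and 0, then 5 and 1, adjusted over the list alone). Under Med12 dsRNA 5 of them rose and 3 fell, and under Med13 dsRNA 3 rose and 1 fell, also adjusted over the list alone. Of the 23 core Mediator genes 2, 3, 6 and 3 rose in the order Cdk8, CycC, Med12 and Med13, and 1, 1, 0 and 0 fell by the limma test, also adjusted over the list alone. In the Toll list 3 and 4 of 11 genes fell and none rose under Cdk8 and CycC dsRNA (5 and 4 adjusted over the list alone), such as the protease gene grass (-0.58 ± 0.07 and -0.47 ± 0.06). Under Med12 dsRNA 4 genes of that list rose and 2 fell, and under Med13 dsRNA 3 rose and 3 fell, also adjusted over the list alone. In the glycolysis list the trehalase gene Treh fell under Cdk8 and CycC dsRNA (-0.57 ± 0.09 and -0.67 ± 0.07), and the aldolase gene Ald1 rose under Med12 and Med13 dsRNA (0.57 ± 0.09 and 0.41 ± 0.09). The small heat shock gene Hsp27 rose under Cdk8 and CycC dsRNA (0.33 ± 0.07 and 0.51 ± 0.05) and fell under Med12 and Med13 dsRNA (-0.37 ± 0.05 in each). In the JNK and cell death list the apoptosome gene Dark did likewise (0.40 ± 0.06, 0.42 ± 0.05, -0.21 ± 0.05 and -0.22 ± 0.05). Under Med12 and Med13 dsRNA kuz of the Notch list fell (-0.50 ± 0.06 and -0.51 ± 0.06). With the same dsRNAs the cytokine receptor gene dome of the JAK/STAT list (0.45 ± 0.06 and 0.30 ± 0.06), the ecdysone coactivator gene tai (0.52 ± 0.08 and 0.39 ± 0.08), wls of the Wingless list (0.30 ± 0.04 and 0.24 ± 0.04) and ap of the epithelial list (0.30 ± 0.07 and 0.27 ± 0.07) rose. In the lamellocyte list CG15347 rose by 0.46 ± 0.06 and 0.90 ± 0.06 and msn fell by a log2 change of -0.42 ± 0.05 and -0.29 ± 0.05 with these dsRNAs. Lists of fewer than 5 measured genes were not tested. Of the nervous system list elav was measured and had log2 values of 0.00, -0.12, 0.29 and 0.06 against controls, of which the third passed the test. Besides bam, the germline list held ovo (0.46 ± 0.11 and 0.36 ± 0.09 under Cdk8 and CycC dsRNA, both past the test). No gene of the muscle and fat body lists was measured over the floor under a single symbol.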

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

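The tests for a mislabelled or wrongly targeted set of Med13 arrays, for a faulty skd probe set and for noise in a set of controls were chosen after the results they concern were seen, and cyclic loess was added after the data were seen, before its own result.

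The transcript of skd fell to 80.6% of controls under Med13 dsRNA, while Cdk8, CycC and kto fell to 14.4% or less under their own dsRNA. If the Med13 arrays held cells depleted of Med12, kto would have been low on them, but it stood at 102% of controls. A single faulty skd probe set is argued against by the second skd probe set, which changed by a log2 value of -0.18 and also shows no deep loss. A correspondingly weak response is argued against too, since the slope of the Med13 on the Med12 fold changes was 0.908 (jackknife SE 0.0306, 2737 genes). What stays open is that both probe sets may read a part of the transcript that outlasts cutting by the dsRNA, or that a small loss of skd mRNA suffices for the response, and neither was tested because the position of the dsRNA is not given in the labels.

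A set of 169 genes moved in opposite directions in the Cdk8 and CycC pair and in the Med12 and Med13 pair, with Pxn, Sp7 and GNBP3 among them. With different controls for the pairs, 106 or 152 genes were opposite, 0.627 and 0.899 of that number. With 4 controls shared by the pairs, 110 (GFP) and 126 (Luc) were opposite. Neither comparison tests an error common to all 8 shared controls. Its effect cannot be told apart, since there are no further controls. On noise in 1 set of controls alone, 100% of the 110 genes chosen against GFP kept both signs against Luc. So did all 126 chosen against Luc when set against GFP (lower 95% exact binomial limits 96.7% and 97.1%, which treat genes as independent). The genes were chosen as past the threshold in all 4 knockdowns, and GFP minus Luc differences had an SD of 0.0761 over all genes. A lost sign was therefore unlikely beforehand, so this does not decide the question. Intensity-dependent scaling is argued against by cyclic loess, after which 149 of the genes (88.2%) kept their calls in all 4 knockdowns. A biological hypothesis that stays open is that the kinase with its cyclin may act on these genes apart from Med12 and Med13, which was not tested, since these arrays do not measure protein.

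The cell cycle and DNA replication genes, with dup, Mcm6 and RnrL, rose as a list under Cdk8 and CycC dsRNA. A bias with intensity is argued against, since the median of the list lay at the 100th percentile of 10000 random lists matched on expression in both knockdowns. A few deviating arrays are argued against as well, since the list mean lay above every control array on 6 of 6 Cdk8 and CycC arrays (10.09 to 10.13 against at most 9.89). The Med12 and Med13 arrays also lay above every control array (9.90 to 9.96). Low values in the shared controls would lift all 4 knockdowns, and this was not tested. In the contrast of the pairs, which uses no controls, 21 genes of the list were lower and 3 higher with Med12 and Med13 dsRNA. The rise was not confined to replication genes. The cyclin genes CycB (0.42 and 0.34 under Cdk8 and CycC dsRNA) and CycB3 (0.40 and 0.28), chosen after their values were seen, rose too. Altered shares of cells in the phases of the cell cycle, or higher transcription of these genes per cell, may each underlie the rise. The arrays cannot separate these because cell cycle phase was not measured here.

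Splits of the arrays into other groups of the same sizes tested whether chance could give as many changed genes, with a fit of those arrays alone. For CycC dsRNA 1 of 100 splits, the real one, reached its 1304 genes, and the highest other split gave 1. For Med12 dsRNA 1 of 100 reached 2468 (highest other 2) and for Med13 dsRNA 1 of 100 reached 1742 (highest other 1). Med12 against Med13 gave 33 genes in 1 of 35 splits (highest other 0), and GFP against Luc gave 2 in 1 of 35 (highest other 1). For the contrast of the pairs 1 of 100 splits reached 2991, and the highest other split gave 881, the cause of which was not tested. Chance assignment of these arrays is argued against by this measure for CycC, Med12 and Med13 dsRNA, for Med12 against Med13 and for the pairs. The measure cannot tell an effect of the dsRNA from a difference between single cultures, since the labels do not say whether the arrays of a group came from separate cultures. Splits that mix the groups also carry the real differences as spread, which lowers their counts. The comparisons with 100 splits used a random draw of those possible. For GFP against Luc the margin is a single gene, and the count moves to 10 without the Luc 4 array, so chance is left open there. The splits took no account of the replicate number, and they were not run for the Cdk8 group, which has 2 arrays.

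A single array far from the other 3 was sought in groups of 4 arrays. The tests covered 46 named genes and 26 summaries, which were list means and the median of the tested genes, in 5 groups. Such arrays were found in 22 of 360 tests, where chance alone gives about 18, since it marks about 1 in 20. For the knockdown targets these were CycC on the CycC 3 array (4.83 against 4.22 to 4.25) and kto on the GFP 2 array (8.70 against 8.68 to 8.69). Among genes of the knockdown responses the array values were 7.67 for CG30148 on Med12 3, 5.28 for CG31445 on Med12 2, 7.16 for Cyp4ac1 on Med13 4 and 6.38 for Ypel on CycC 1. CG44014 stood at 5.25 on Med13 3 (others 6.29 to 6.46) and at 7.34 on GFP 3. On GFP 3, CG5001 stood at 5.14 and CG9098 at 3.13, below the floor. The actin-bundling gene sn stood at 8.66 on GFP 4, CG10939 at 5.09 and Epac at 4.98 on Luc 1, and fbp at 4.78 on Luc 2. The list means were 8.68 for antimicrobial peptides on Luc 4, 9.68 for the Imd pathway and 9.56 for glycolysis on Med13 3, and 9.51 for crystal cell genes on Med12 4. They were 8.58 on CycC 2 and 8.48 on Luc 1 for ecdysone genes, 10.4 for lipid synthesis on Luc 1 and 8.73 for epithelial genes on Med13 4. The most by array were 4 on Luc 1 and 3 each on GFP 3 and Med13 3.

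Probe sets outside the tested genes also responded. Of 684 over the floor with no gene name here, 131 changed under Cdk8 dsRNA, 146 under CycC, 253 under Med12 and 203 under Med13 dsRNA, against 0 by limma between GFP and Luc. Of 202 that match several genes, 29, 34, 76 and 65 changed in the same order, against 0 by limma between GFP and Luc. These probe sets were not analysed further here.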

How the results depend on the processing

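Leaving out both Luc 1 and Luc 2, cyclic loess, list tests under other scalings, single arrays left out of the correlations, the alternatives for the targets and the permutation of replicate numbers were chosen after seeing the data.

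Of 498 named gene results 326 passed the threshold, and 0 reversed under the alternatives applied to them. Cyclic loess and a fit of every probe set were not applied to these results. Quantile normalization kept 315, median centring 318, no filter 314, the mean of probe sets 326, array weights 323, the trended robust prior 326 and fits of only the groups compared 312. The replicate number as a block kept 324. A change of at least 2-fold was met by 100 of the 326. A floor of 6 kept 311 of 311. With GFP or Luc controls alone 273 and 282 of 297 were kept, with the controls as 1 group 295 of 297, and without Luc 1 and Luc 2 316 of 326. Leaving out 1 array kept 307 to 322.

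Leaving out 1 array gave 538 to 1180 changed genes for Cdk8, 1141 to 1510 for CycC, 2146 to 2557 for Med12, 1569 to 1957 for Med13, 2 to 10 for GFP against Luc, 25 to 69 for Med12 against Med13, 3 to 8 for Cdk8 against CycC and 2462 to 3012 for the pairs. The lowest Cdk8 count has a single Cdk8 array. A change of at least 2-fold was met by 35, 29, 72 and 55 genes for Cdk8, CycC, Med12 and Med13, by 101 between the pairs, 2 between Cdk8 and CycC, 1 between Med12 and Med13 and 0 between GFP and Luc (limma, 331 at unadjusted p under 0.05). It also ended the call of skd in Med13 (-0.31), by construction.

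GFP against Luc gave 4 genes after quantile normalization, 4 after median centring and 12 with array weights. Med12 against Med13 gave 88 with array weights. The cause was not tested. Fits of only the groups compared, with fewer arrays, gave 33 for Med12 against Med13 and 3 for Cdk8 against CycC. With the replicate number as a block GFP against Luc gave 5 genes. Each other count of changed genes stayed within 1.5 times. The labels do not say that the number pairs the arrays, and 15 of 40 same-number pairs had residual r of 0.1 or less (-0.107 to 0.436), with all pairs over it in 1 of 10 pairs of groups. As a hint from the data, 13 of 20 arrays correlated best with their own number, where permuted numbers gave a mean of 5.01 (p = 0.00380), and the mean r of same-number pairs was 0.112 (p = 0.000200, 10000 permutations). Arrays of one number thus shared some deviation, and its source was not tested.

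With split controls the correlation was 0.793 or 0.800 for Cdk8 with CycC and 0.881 or 0.887 for Med12 with Med13. With Cdk8 or CycC against Luc it was 0.0662 and 0.0536 for Cdk8 with Med12 and Med13 and 0.0495 and 0.0380 for CycC. With CycC against GFP 197 genes were opposite to Med12 and 170 to Med13 (294 and 252 with CycC against Luc), 4 were opposite between Med12 and Med13 (1 the other way), and 106 between the pairs (152 the other way). These counts were lower than with all controls except that between Med12 and Med13, which went from 1 to 4 or stayed at 1. The cause was not tested.

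Camera with an estimated correlation called 3 lists for Cdk8, 3 for CycC, 1 for Med12, 1 for Med13 and 0 for the pairs, where the preset called 7, 6, 7, 9 and 5. Fry, which does not compare a list with other genes, called 12 for Cdk8, 12 for CycC and 16 for the pairs. Of the 34 list calls 0 changed direction under 3 scalings, but 7 were lost after quantile normalization, 3 of these also after median centring and 6 after cyclic loess. Signal over background limits genes near the floor, and at a log2 change of 0.25 the simulated recovery was 52.2% for Cdk8.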

Other observations

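The families of genes, their tests and the genes named here were chosen after the results were seen, while the test of neighbouring genes was written before its result.

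Neprilysin-like genes, which encode membrane and secreted peptidases, fell under Cdk8 and CycC dsRNA. Of 7 measured, 5 fell under Cdk8 dsRNA (camera adjusted p = 5.20e-05 over 78 families sharing a symbol stem) and 6 under CycC dsRNA (1.13e-05). With an estimated correlation these became 0.460 and 0.320. Nepl19 changed by log2 values of -0.97, -0.83, -0.76 and -0.59 in the order Cdk8, CycC, Med12 and Med13, and Nepl20 by -0.72, -0.71, -0.16 and -0.24. Nepl9 fell with Cdk8 and CycC dsRNA (-0.45 and -0.48) and rose with Med12 and Med13 dsRNA (0.49 and 0.53). The fall was not particular to Cdk8 and CycC dsRNA for every member. Nepl4 (-0.42, -0.54, -1.31 and -0.91 in the same order) and Nepl21 (-0.30, -0.30, -0.64 and -0.47) fell more with Med12 and Med13 dsRNA. Of 19 nucleoporin genes, whose products form the nuclear pore, 8 rose and none fell under Cdk8 dsRNA (0.00179, and 0.697 with an estimated correlation) and under CycC dsRNA (0.00474, and 0.828), with Nup205 at 0.28 and 0.25. No direction of these families flipped under 3 scalings.

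Under Med12 dsRNA, 13 of 69 mitochondrial ribosomal protein genes fell and 2 rose (camera adjusted p = 0.0278, and 0.890 with an estimated correlation), and 10 of 21 genes of RNA polymerase subunits fell (0.0278, and 0.865). All 6 genes of the signal recognition particle, which brings nascent secreted proteins to the endoplasmic reticulum, were lower with Med12 and Med13 than with Cdk8 and CycC dsRNA (0.0226, and 0.921). The FGF ligand gene bnl fell in all 4 knockdowns (-0.66, -0.78, -1.30 and -1.64), and so did aos, which encodes the secreted EGF receptor inhibitor Argos (-0.58, -0.69, -0.78 and -0.61).

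A hypothesis tested here is that neighbouring genes respond together. Among 5939 pairs of adjacent tested genes, 642 changed in the same direction under Med12 dsRNA, where 10000 shuffles of gene order gave a mean of 558, and 222 under CycC dsRNA against a mean of 176. Without pairs of the same symbol stem, 5874 pairs were left and the lower of both percentiles was 99.8. This cannot decide whether copies of one gene that share probe sequence contribute. Copies with separate CG numbers or different names stayed in, and probe sequences were not compared. Shared local regulation may contribute, and so could genes of like function lying side by side, which was not tested.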
